A study of Mus musculus with 2 samples.

How the data were processed

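Spleen cells of wild-type and TLR9-deficient NOD mice aged 6 to 7 weeks were sorted for the T cell receptor beta chain, per the labels' protocols. The sorted T cells of several mice were pooled per genotype, and 1 pool of each genotype was hybridised, so the comparison rests on 2 arrays. Per the labels' protocols, total RNA was taken with a column kit and amplified to biotin-labelled cRNA, which was read on an Illumina mouse expression bead array. The software, the background treatment and the normalization step are not given in the sources used here.

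The authors deposited 1 intensity per probe and array on a linear scale. Each signal stands beside a detection p-value, per the file headers, which sets the probe against the negative-control beads of its array. Although deposited as non-normalized, the intensity columns were already matched between arrays. Once sorted, the columns differed by at most 0.015 on the log2 scale over 46632 probes. No background had been subtracted, since the lowest intensity was 19.4 on either array and the median was 32.9. The second deposited table of intensities held exactly the same values, with no tolerance, for 100% of the probes and served only as an alternative. That alternative left out the background correction and the quantile step described below, so it is no independent check.

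Background was corrected with the normexp model in limma 3.58.1 (R 4.3.3), with the mean and SD of the negative controls inferred from the detection p-values. The inferred control mean was 31.4 with an SD of 3.61 on the wild-type array and 31.5 with an SD of 3.81 on the TLR9-deficient array. An offset of 16 was added, the arrays were quantile-normalized and log2 was taken. A probe counted as detected at a detection p under 0.01. The difference is TLR9-deficient minus wild type, and a 2-fold difference was the threshold for counts. With 1 array per genotype there is no replicate spread, no test and no p-value across probes. The number of arrays limits the precision of every value. For the probes of Tlr9 and Nt5e, a robust SD of the differences of the 500 probes nearest in mean signal serves as a yardstick; it holds biological and technical differences together. Later steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

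Gene labels came from the platform annotation, paired with the probes by identifier. Of the probes, 29976 had 1 gene label, 10 had several and 16646 had none. Symbols were brought up to date through the gene identifier with a table of assembly GRCm38.p6, which held the identifier of 29921 labelled probes. The files name no genome build, so no coordinate is printed, and the table served only for names and for which genes neighbour each other. One probe per gene was taken, that with the highest mean. Fixed lists of genes were summarised by the median difference of their detected members, with its percentile among 10000 random lists of the same size drawn within 20 bins of mean signal. A list with at least 5 detected members stood apart below the 2.5th or above the 97.5th percentile, which describes these 2 arrays and is no test of genotype. The same was done for the median absolute difference of genes within 5 Mb and 20 Mb of Tlr9.

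The pairing of labels and values was checked in 4 ways, which were chosen after the values were seen, apart from the restriction of 1 of them to probes with a current accession, which was set before its result was seen. They were the detection of labelled families, the signals of labels of abundant transcripts, the rank correlation of probes sharing a label, and the mean signal of a family read at up to 300 rows before or after its labels. Families were matched on symbols, kept within 150 rows of their median row, and needed 8 probes. The brightest reading of each family was set against that of the same row pattern at 1000 random places over 1000 rows away. Intervals of shares are 95% Wilson intervals over probes, which are not independent replicates. Intervals of correlations come from 500 resamples of genes. These checks did not bear the labels out probe by probe. The rule written beforehand, which names the 15 genes with the largest difference in each direction, was therefore not applied. At most 2 probes per direction are given by identifier, those with the largest difference among probes detected on both arrays. Values at gene labels are values of probes so labelled, and no gene was renamed from its row.

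The steps were tested on simulated data. For the gene counts over 7061 genes, 53% of 100 genes moved by 1 on the log2 scale and 99% of 100 genes moved by 2 were counted at 2-fold. For the list medians over the same genes, a list of 15 genes moved by 0.5 came out at percentile 100, and 5% of 200 unmoved lists stood apart. Genes were drawn independently there, so links between adjacent rows were not simulated. For the same-label probes over 46632 rows, values drawn with a correlation of 0.3 within genes gave 0.28 across 5548 distant pairs. They gave 0.012 once all values were moved by the same 40 rows.

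The groups, the settings, the lists and the alternatives were fixed before the data were examined. The alternatives were no background correction, median scaling, no normalization between arrays, cyclic loess, an offset of 1 or 64, detection on both arrays, detection at p under 0.05, no detection filter, the mean of all detected probes of a gene, the second deposited table, thresholds of 1.5-fold and 3-fold, random lists not matched on signal, and windows of 2 and 10 Mb. Counts of single probes, the same counts over probes with a mean intensity of at least 100, the 4 single probes and the bright probes without 1 block of adjacent rows were added after the data had been seen.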

Results

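Gene expression was compared between splenic T cells of NOD mice, a strain that develops autoimmune diabetes spontaneously, with and without Toll-like receptor 9 (TLR9), an endosomal receptor for unmethylated CpG DNA. The series title places TLR9 deficiency beside T cell expression of CD73, the ecto-5'-nucleotidase encoded by Nt5e. One array of pooled, sorted T cells stood for each genotype, so no difference given here has a replicate check. Each array carried 46632 probes. At a detection p under 0.01, 11505 probes were detected in the wild-type pool and 11616 in the TLR9-deficient pool. Both arrays detected 10740 probes, 23.0% of all, and at least 1 array detected 12381.

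Probes labelled with the targeted gene came first. Of the 2 probes labelled Tlr9, one read 110 in the wild-type pool and 129 in the TLR9-deficient pool, a log2 difference of 0.26 against a spread of 0.27 among probes of like signal. The other was detected in the wild-type pool only. It read 44.8 there and 41.3 in the TLR9-deficient pool, where it missed the detection threshold. Set against the lowest detected value of that array, it was at least 1.096-fold lower in the TLR9-deficient pool. Its log2 difference of -0.18 lay within the spread of 0.23 among probes of like signal, so it is not shown to be lower. The labels do not say which part of the gene was deleted, and a probe outside that part does not check the genotype. The probe labelled Nt5e read 142 in the wild-type pool and 161 in the TLR9-deficient pool, a log2 difference of 0.21 against a spread of 0.29. Of the detected probes, 50.9% had a smaller difference than it in either direction. The pair of probes detected on both arrays, 1 labelled Tlr9 and 1 labelled Nt5e, thus differed by less than the spread. The gene labels of the table were not borne out probe by probe.

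Gene labels were set against detection in these sorted T cells. The T cell identity list, which holds the CD3 chains and the kinases and adaptors of T cell receptor signalling, had 4 of 32 labelled probes detected on both arrays, 12.5% (95% Wilson interval 4.97% to 28.1%). The B cell list had 5 of 31 probes detected (16.1%, interval 7.09% to 32.6%), and the pancreatic exocrine list, whose digestive enzymes belong to another organ, had 8 of 20 (40.0%, interval 21.9% to 61.3%). Over all labelled probes the share was 25.6%. Other T cell lists lay above it, with 4 of 10 probes of the CD4 lineage (40.0%, interval 16.8% to 68.7%), 3 of 9 of the CD8 lineage (33.3%, interval 12.1% to 64.6%), 14 of 38 of activated and memory T cells (36.8%, interval 23.4% to 52.7%), 13 of 30 of cytotoxic and Th1 effectors (43.3%, interval 27.4% to 60.8%) and 8 of 16 of Th17 cells (50%, interval 28.0% to 72.0%). Naive and central memory labels lay below it, with 6 of 42 (14.3%, interval 6.72% to 27.8%), and regulatory T cell labels had 10 of 44 (22.7%, interval 12.8% to 37.0%). Th2 labels had 3 of 12 (25%, interval 8.89% to 53.2%) and follicular helper labels 5 of 18 (27.8%, interval 12.5% to 50.9%). Among lists of other cells the share ran from 14.3% for NKT and NK cells, 15.4% for dendritic cells, 18.2% for macrophages and monocytes and 22.2% for both plasma cells and stroma to 27.3% for neutrophils and 42.3% for erythroid cells and platelets. Labels of transcripts abundant in T cells, chosen after their values were seen, were Cd3d, Cd3e, Cd3g, Thy1 and Ptprc for T cell surface proteins and Actb, Gapdh, B2m and Eef1a1 for general ones. They covered 21 probes, of which 3 were detected on both arrays, and the highest signal among them was 53.9. Of the 2 probes labelled B2m, the light chain of class I major histocompatibility molecules, the brighter in each pool read 36.3 and 39.3, below the lowest signals at which probes were detected, 42.4 and 42.2.

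**Figure D1:**
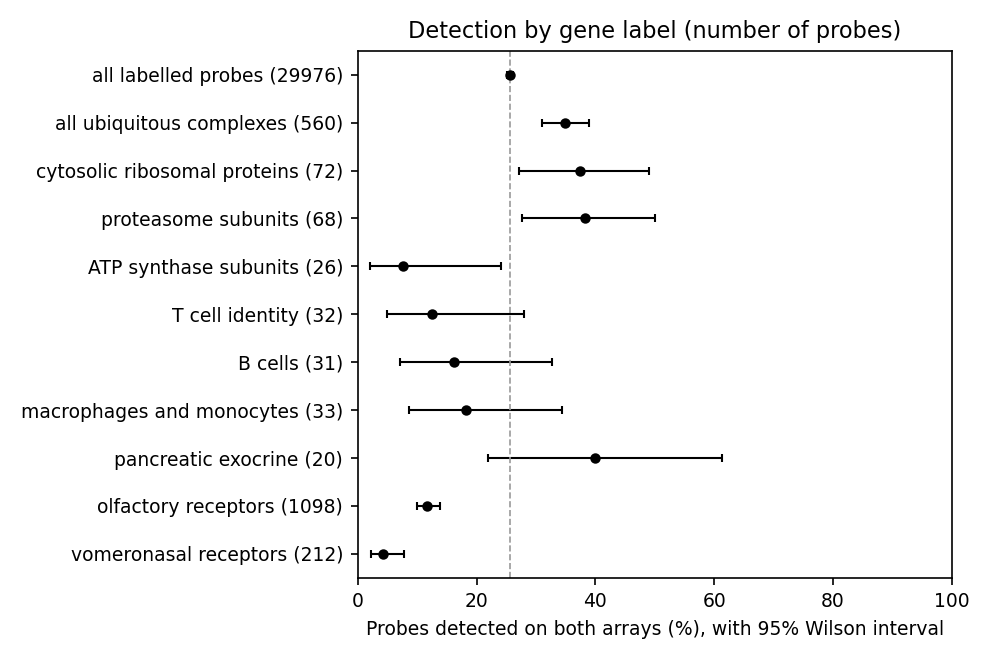
Share of probes detected on both arrays (percent, points) with 95% Wilson intervals (bars) by the gene label of the probe, with the number of labelled probes in parentheses and the share over all labelled probes (25.6%) as a dashed line. T cell identity labels lie at 12.5% and pancreatic exocrine labels at 40.0%, with intervals that overlap.

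Families that all cells express, pooled, were detected more often than the average label, yet in a minority of their probes. Of 560 probes labelled as subunits of 15 ubiquitous families, among them the ribosome, the proteasome and the respiratory complexes, 195 were detected on both arrays (34.8%, interval 31.0% to 38.9%). Cytosolic ribosomal proteins reached 27 of 72 probes (37.5%, interval 27.2% to 49.0%) and proteasome subunits 26 of 68 (38.2%, interval 27.6% to 50.1%), and the families ranged from ATP synthase subunits, with 2 of 26 (7.69%, interval 2.14% to 24.1%), to splicing factor 3 subunits, with 9 of 15 (60.0%, interval 35.7% to 80.2%). Olfactory receptor labels reached 129 of 1098 (11.7%, interval 9.98% to 13.8%) and vomeronasal receptor labels 9 of 212 (4.25%, interval 2.25% to 7.87%). Probes that share a gene label but lie over 500 rows apart in the table had a rank correlation of signal of 0.00017 across 5548 pairs from 2337 genes (95% interval -0.031 to 0.032), a correlation across probes, which are not independent replicates.

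Signals of labelled families were also read at rows before and after their labels. Rows follow the alphabet of the labels in 86.9% of neighbouring pairs, so that a family forms a block. Read at their own rows, 50 probes labelled as cytosolic ribosomal proteins had a geometric mean signal of 111, and the brightest reading within 300 rows was 352, at 49 rows earlier. The brightest of so many readings lies above the first by construction, so the same pattern of rows was also placed at 1000 random places of the table. The median of the brightest readings there was 69.4, and none of the 1000 reached 352. Proteasome labels read 66.3 at their own rows and 155 at 41 rows earlier, which 16 of 1000 random places reached. Those of the other 13 families were reached by 38 to 654 of the 1000 random places and did not stand out on their own. ATP synthase labels, for example, went from 37.0 to 217 at 144 rows earlier, which 148 of 1000 random places reached. Of the 15 families, 14 had their brightest reading before their labels and 1, the outer membrane translocases, after them. The distance differed between families and, after the early rows, mostly shrank along the table. It was 127 to 168 rows for chaperonin, ATP synthase and vacuolar ATPase labels, at middle rows 11490 to 14678. Cytochrome c oxidase and initiation factor 3 labels, at rows 15922 and 19877, had 209 and 205. At rows 30891 to 41416 it was 34 to 77, and inner membrane translocases, at row 43101, had 98. This order was not tested. No single shift stood out among same-label probes, but a scan for 1 common shift cannot find a distance that changes. Among same-label probes within 3 rows of each other, the rank correlation was 0.16 at the rows as deposited, and 87 of 600 other shifts gave a higher one. Genes are therefore not named below as higher or lower.

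**Figure D2:**
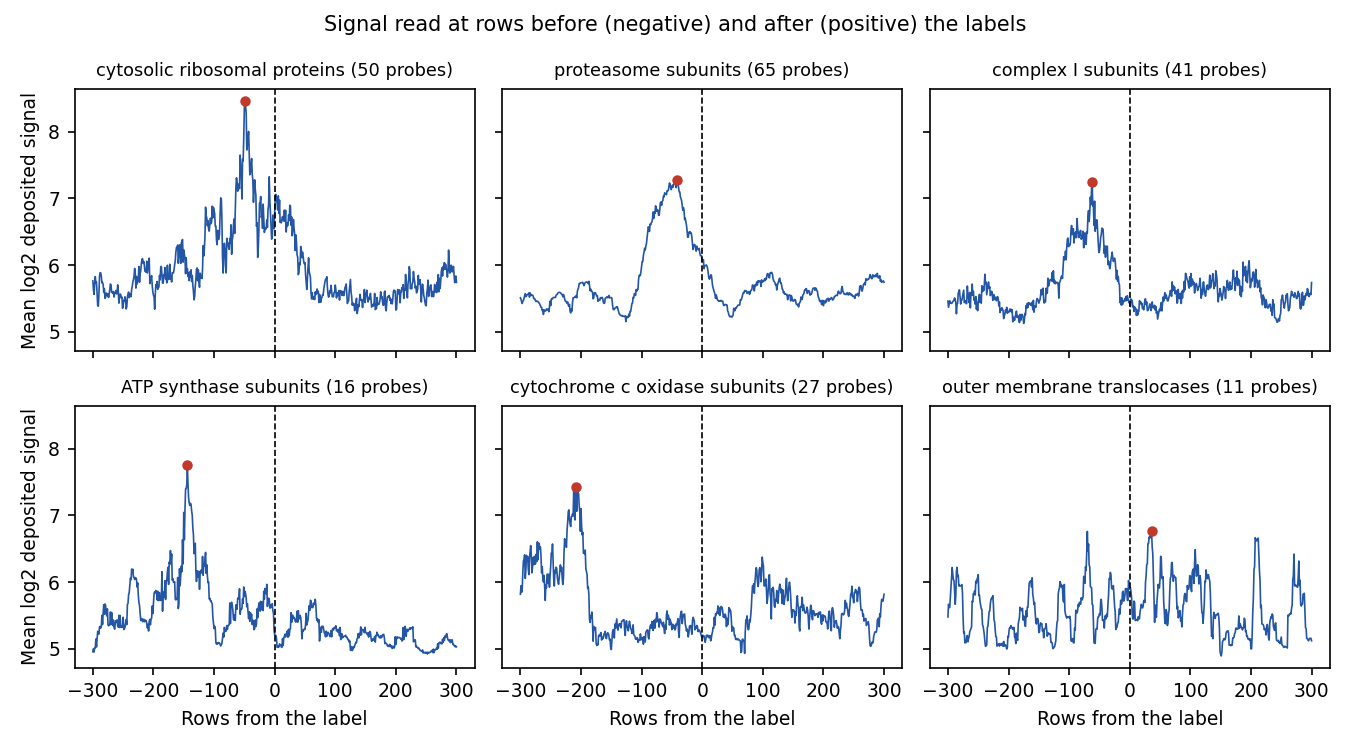
Mean log2 deposited signal (vertical axis, both arrays averaged) of the probes of 6 labelled families when read at rows before (negative) or after (positive) their labels (horizontal axis, rows). The dashed line marks the rows as deposited and the red point the brightest shift, which is -49 rows for cytosolic ribosomal proteins and -209 rows for cytochrome c oxidase subunits; the outer membrane translocases, at 36 rows, have no single clear peak.

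The arrays themselves were close to each other. Across probes detected on both, the log2 values correlated with Pearson's r = 0.976, and the robust SD of the differences was 0.27. It was 0.079 among probes detected on neither array, where values lie near the background and Pearson's r was 0.61. Background correction and the offset hold those values close together, so 0.079 is no measure of noise for detected probes. At least 2-fold higher in the TLR9-deficient pool were 123 probes, and at least 2-fold lower were 120, together 1.96% of the probes detected on at least 1 array. Differences of at least 4-fold were seen at 5 probes in the higher and 8 in the lower direction. These counts depend on how weak signals are treated. Without background correction they were 31 higher and 51 lower, and with an offset of 1 they were 484 and 464. Under the main setting and all 6 other background, offset and scaling settings, 22 probes were at least 2-fold higher and 38 at least 2-fold lower.

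**Figure D3:**
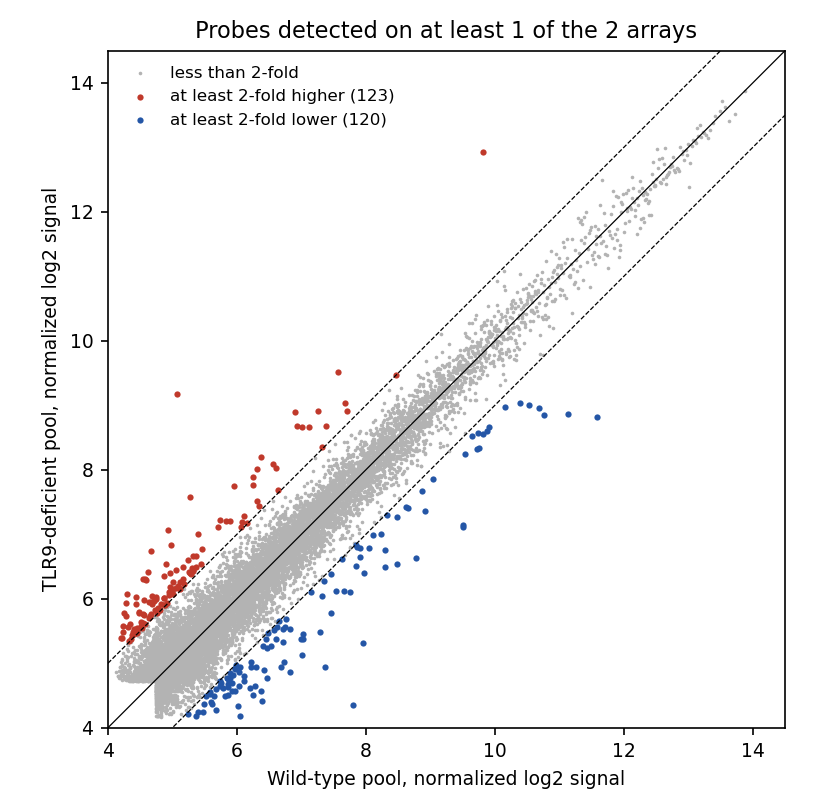
Normalized log2 signal of the wild-type pool (horizontal axis) against the TLR9-deficient pool (vertical axis) for the 12381 probes detected on at least 1 array, 1 point per probe. The solid line marks equal signal and the dashed lines a 2-fold difference; 123 probes (red) lie above and 120 (blue) below them, and among probes with a mean signal of at least 300 detected on both arrays 9 were higher and 21 lower, 8 of the 21 in 1 block of adjacent rows.

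Among the 1596 probes detected on both arrays with a mean signal of at least 300, 9 were at least 2-fold higher and 21 at least 2-fold lower in TLR9-deficient T cells. Of the 21, 8 lay in 1 block of adjacent rows, and 13 were left without it. Among the 5999 with a mean signal under 100, 43 were higher and 34 lower. Probe identifiers are given as they stand beside the values, with the same limit as the labels. The largest difference upward among probes detected on both arrays was at probe ILMN_2497657, which read 49.3 in the wild-type pool and 596 in the TLR9-deficient pool, a log2 difference of 4.11. As the wild-type signal lies near the background, this value moved with its treatment, to 3.23 without background correction, 2.95 with an offset of 64 and 4.93 with an offset of 1. Probe ILMN_1214788 read 915 and 7777, an 8.63-fold difference. Downward, probe ILMN_1241196 read 3093 in the wild-type pool and 467 in the TLR9-deficient pool, a log2 difference of -2.77, and probe ILMN_1244922 read 265 and 55.7, a log2 difference of -2.64 that became -1.97 without background correction, -1.76 with an offset of 64 and -3.23 with an offset of 1. A further 876 probes were detected in the TLR9-deficient pool alone and 765 in the wild-type pool alone. Set against the higher of the dim probe's own value and the lowest detected value of its array, 23 of the former were at least 2-fold higher and 21 of the latter at least 2-fold lower in TLR9-deficient T cells.

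Counted by label, 82 genes were at least 2-fold higher and 59 at least 2-fold lower among 7061 labelled genes detected. Without background correction these counts were 23 and 25. Of 31 fixed lists, 25 had at least 5 detected members, and their medians lay between -0.33 and 0.26. Labels of B cell genes had a median of -0.33 over 5 members, at percentile 1.80 of random lists. Labels of activated and memory T cell genes had a median of 0.26 over 9 members, at percentile 98.4, and labels of NF-kappaB targets and regulators a median of 0.19 over 14 members, at percentile 98.6. These 3 lists stood apart where 1.25 would by chance if genes varied independently, and none of them stood apart under every alternative. Labels of a list can lie in adjacent rows, where differences of detected probes had a rank correlation of 0.15. The random lists did not keep this link, so 1.25 may be too low. The activated and memory median turned to -0.043 with no detection filter. Labels of the adenosine and extracellular purine list, which holds Nt5e, had a median of 0.051 over 7 members, at percentile 64.4. Labels of regulatory T cell genes had a median of -0.058 over 9 members, at percentile 31.2. As the labels are not borne out, these values describe probes that carry the labels and not the genes.

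The neighbourhood of Tlr9 was examined because a targeted mouse crossed to another strain can carry donor DNA around the target, and Nt5e lies on the same chromosome, 9. Within 5 Mb of Tlr9, 68 labelled genes were detected, with a median absolute log2 difference of 0.19 at percentile 39.9 of random lists. Within 20 Mb there were 139, with a median of 0.21 at percentile 64.4. Neither window stood apart, with the same limit on the labels.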

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

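The counts of probes, the counts limited to bright probes and the 4 single probes were chosen only after the data had been seen; the other alternatives were planned. Weak signals limit the counts, since the median signal of 32.9 lies close to the inferred background mean of 31.4. No paired analysis was possible because each genotype had 1 array. Median scaling, no normalization, cyclic loess, detection at p under 0.05 and no detection filter left each count of genes and probes within 1.5 times its main value, and so did the mean of detected probes for genes. The counts of at least 2-fold higher and lower were 82 and 59 genes, and 123 and 120 probes. They became 23 and 25 genes, and 31 and 51 probes, without background correction. The second deposited table gave the same counts because it holds the same values and was also run without background correction. With an offset of 1 they were 253 and 213 genes, and 484 and 464 probes; with an offset of 64 they were 15 and 18 genes, and 22 and 38 probes. Requiring detection on both arrays left 49 genes and 76 probes higher. At 1.5-fold the counts were 296 and 248 genes, and 532 and 493 probes; at 3-fold they were 18 and 6 genes, and 24 and 28 probes. Over probes with a mean signal of at least 100 they were 33 and 53. The number of lists apart, 3, fell to 1 without background correction and to 1 with detection on both arrays. It was 2 with an offset of 64, detection at p under 0.05, no detection filter and the mean of detected probes. It was also 2 with the second deposited table, which was run without background correction. The cause was not tested. In these settings only the NF-kappaB labels of the 3 stayed apart, except that with the mean of detected probes the other 2 did. Where 2 stood apart otherwise, the second was dendritic cells (offset of 64, second table), TLR signalling (p under 0.05) or neutrophils (no filter). The median of the activated and memory T cell labels, 0.26, turned to -0.043 with no detection filter, which adds undetected members. That of the B cell labels, -0.33, became -0.027 with no detection filter, -0.072 with detection at p under 0.05, -0.17 without background correction, -0.13 with an offset of 64 and -0.61 with an offset of 1. Of 297 list medians recomputed, 281 kept their side of the percentile limits. Most of these belong to lists that did not stand apart in the main setting. Keeping a side does not mean keeping the sign. On the log2 scale, the brighter probe labelled Tlr9 gave 0.18 to 0.31, the dimmer one, detected in the wild-type pool only, -0.41 to -0.066, their mean 0.041, and the probe labelled Nt5e 0.15 to 0.23, each moving by less than the spread of probes of like signal. Genes around Tlr9 stood apart under no alternative or window, with medians of 0.088 to 0.25. All 40 values of the 4 probes kept sign and were at least 2-fold, but detection filters cannot alter any.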

Other observations

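The tests of displaced rows, their random places, and of other cells, and the values of neighbouring rows, were chosen only after the result was seen. The test of out-of-date annotation was set before its own result was seen. It used a part of the distant pairs tested for other cells, so it is not independent of that test. Probes that differed lay near one another in the table. Of the 123 probes at least 2-fold higher, 19 were followed within 10 rows by another such probe, against a mean of 3.98 and a highest value of 11 in 1000 random draws from the detected probes. Of the 120 at least 2-fold lower, 27 were, against a mean of 3.77 and a highest of 10. Across detected probes in adjacent rows the differences had a rank correlation of 0.15 over 4765 pairs, and 50 rows apart it was -0.00062 over 3731 pairs. Probes with a shared label often lie close together, with 13324 such pairs within 3 rows, and the random draws did not keep them together. Neither the excess nor the correlation can therefore be told apart from several probes of the same gene. In the longest block, 9 probes within 13 rows were 2.17-fold to 2.93-fold brighter in the wild-type pool, with signals of 375 to 976 there and 170 to 420 in the TLR9-deficient pool. Which genes these rows measure was not worked out.

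The signals followed the gene labels only in part, with 34.8% of probes detected for ubiquitous families against 11.7% for olfactory receptors but no shared level among distant probes of 1 label, and 3 explanations were weighed. Other cells in the pools, with rows in register, would leave probes of 1 gene at a shared level. Distant probes with the same label had a rank correlation of 0.00017 (95% interval -0.031 to 0.032). Distant pairs were a selected set, as 13324 other same-label pairs lay within 3 rows, and their correlation in register is not known. Displaced rows bring the value near 0 whatever the cells are, as in the simulation (0.012). The value therefore cannot decide whether other cells were present. Degraded RNA is left open as well, since it can lower probes of 1 gene unequally. Out-of-date annotation would spare probes whose accession is still a transcript of the labelled gene, but 1355 distant pairs of such probes correlated at -0.017 (interval -0.070 to 0.042). Displaced rows would bring this value near 0 too, so it bears only on out-of-date annotation with rows in register. A further hypothesis is that identifiers and values came out of register before deposit. Of 15 families, 14 were brightest more than 5 rows before their labels and 1 after. An exact two-sided sign test over families, which are not independent, gave p = 0.00098. For 13 of the 15, though, the brightest reading itself was reached at 38 to 654 of 1000 random places. No explanation by genotype was tested, since the pattern was read from the mean of both arrays and the genotypes do not enter it.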
